A study of Mus musculus with 6 samples.

How the data were processed

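Polyadenylated RNA from primary neonatal mouse cardiomyocytes was sequenced in 6 libraries, 2 for each of 3 treatments: phosphate-buffered saline (PBS), BMP2, and BMP2 together with dorsomorphin (BMP2+DM). The labels name each library's treatment and replicate number. They do not say whether the replicates came from separate cultures or animals, so p-values of single genes measure only the spread between these samples. Dose and duration of treatment are not given in the sources used here.

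The authors deposited whole-number read counts per gene symbol, 1 file per library. Per the submitters' processing notes, FastQC, Trimmomatic, STAR, HTSeq and DESeq2 were used with the mm10 mouse genome, with no versions named. The gene annotation, the strand setting of the counting step and the read layout are not given in the sources used here. The extraction and library protocol in the labels describes second-strand synthesis and adaptor ligation and names no strand-marking step. The last 5 lines of each deposited count file are summary lines that name no gene. They held between 53.8% and 54.2% of each file's total and were left out of library sizes and tests. Of each total, 49.7% to 50.2% was assigned to no feature and 3.80% to 4.39% to reads without a unique alignment.

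Counts on genes were 14366042 and 11652488 in the PBS libraries, 11132019 and 10362486 in the BMP2 libraries, and 10140668 and 10106667 in the BMP2+DM libraries. Each file lists 32245 gene symbols, of which 31424 (97.5%) were found in GENCODE vM21, an annotation of the same genome build. Gene positions come from that annotation. No count was recorded in any library for 11888 symbols. The edgeR filter filterByExpr, with its minimum count of 10 and minimum total count of 15, left out 5979 more, and 14378 genes were tested.

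All 6 libraries were fitted together with group means and no covariate, leaving 3 residual degrees of freedom. The test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with TMM factors, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Values are given as log2 fold change ± standard error, the standard error being the absolute log2 fold change divided by the square root of F. Levels are counts scaled by TMM-adjusted library size (CPM), as mean ± SD over 2 libraries. The common biological coefficient of variation was 0.0872. The 2 libraries of each group differed by more than sampling noise and were treated as separate samples. Chi-square per degree of freedom was 13.6 for PBS, 17.2 for BMP2 and 3.84 for BMP2+DM. These sums include the ribosomal-repeat models Gm42418 and AY036118. They held 1.31% of gene counts in PBS 1 and 0.0702% in PBS 2, and 2.10% in BMP2 1 and 0.0928% in BMP2 2. The higher values for PBS and BMP2 therefore do not measure the spread of genes at large.

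Gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Of 33 lists, 31 had at least 5 tested members and were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists. Erythroid genes had 0 tested members, and Schwann cell and neuronal markers had 4, so neither was tested as a set. At the preset correlation, camera weighs a list's members against the other tested genes. Those p-values measure spread across genes, not the spread between the 2 libraries of a group. With an estimated correlation, camera also takes its degrees of freedom from the 3 residual ones. Its p-values then rose even where the estimate lay below the preset, as for BMP-SMAD targets (−0.0307) and sarcomere genes (−0.0314). Genes are named where they are among the 8 largest rises or 8 largest falls past the threshold (5 and 5 for BMP2+DM against PBS), with mean log2 CPM of at least 2 and groups that do not overlap, leaving out predicted genes and pseudogenes. Up to 4 members per list with the smallest p, and a fixed panel of 13 genes, are also named.

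Fold changes that share the BMP2 or PBS libraries are correlated by construction. The overlap of calls and the covariance of fold changes were therefore set beside 20 simulations with no effect in any group, 20 with the BMP2 effects as fitted and dorsomorphin without effect, and the overlap of independent lists. The test was also tested on simulated data, with 200 genes changed per run in 5 runs of the BMP2 against PBS comparison over 14378 genes. It recovered 82.8% of genes raised 2-fold, 66.4% of genes lowered to 0.5, 59.6% of genes raised 1.5-fold and 50.4% of genes lowered to 0.667. None had the wrong direction, and 67 of 760 calls (8.82%) fell on unchanged genes, more than the nominal 0.05. Of lists of 20 genes, 5 of 5 shifted 1.4-fold and 0 of 150 unshifted were called. Genes were drawn independently in these simulations. The list result therefore does not cover lists with correlated members, such as mitochondrially encoded genes (estimated correlation 0.519).

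Alternatives were RLE factors, no count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, the libraries of 2 groups alone, robust dispersion, a minimum fold of 1.5, an estimated correlation for lists, and leaving out each library. After the data were seen, 2 more were added: leaving out the 2 libraries with high counts on ribosomal-repeat gene models, and leaving those models and Lars2 out of the counts. Figures and tables were made with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.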

Results

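The data were gene-level read counts from primary cardiomyocytes of newborn mice treated with PBS, with BMP2, or with BMP2 and dorsomorphin, 2 libraries each. BMP2 is a secreted growth factor that acts through BMP receptors and SMAD transcription factors. Dorsomorphin is a small molecule that inhibits BMP receptor kinases and is also known as an inhibitor of AMP-activated protein kinase. Counts on genes ran from 10106667 to 14366042 per library. The first principal component of log2 CPM, with 42.8% of the variance, separated PBS from the other libraries. The second, with 23.5%, separated BMP2 from BMP2+DM. The libraries PBS 1 and BMP2 1 held 1.31% and 2.10% of their gene counts on the ribosomal-repeat models Gm42418 and AY036118, against 0.0702% to 0.0928% in the other 4.

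BMP2 against PBS asks which transcripts BMP2 changes in cardiomyocytes. The labels name no batch, so any other difference between the PBS libraries and the rest is included. Interferon-stimulated genes were the group with the greatest fall: 20 of 20 tested members fell, also 20 adjusted over the list alone, with a median log2 fold change of −2.30 (camera adjusted p = 4.51e-20, and adjusted p = 0.0458 with an estimated correlation). Ifit3, which encodes an interferon-induced antiviral protein, went from 64.8 ± 1.02 to 4.86 ± 1.87 CPM (SD, n = 2), a log2 fold change of −3.73 ± 0.19; the gene lies on the plus strand of chromosome 19 (34583531 to 34588731, mm10). Ifit1 fell by 3.63 ± 0.19 on the log2 scale and Cxcl10, a chemokine gene induced by interferon, by 3.50 ± 0.20. Axin2, a target and feedback regulator of Wnt signalling, had the greatest rise of the named genes, from 0.678 ± 0.15 to 23.6 ± 0.879 CPM, or 34.8-fold (log2 5.12 ± 0.26, edgeR adjusted p = 1.65e-10). Its raw counts were 8 and 9 with PBS, and 253 and 254 with BMP2. The gene lies on the plus strand of chromosome 11 (108920349 to 108950783, mm10).

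The other largest rises were Igfbp5, an insulin-like growth factor binding protein gene (7.28-fold), Ndnf (5.84-fold), Mrgprf, Itih5 (4.78-fold), Rec8 (4.71-fold), Fst, which encodes the activin and BMP antagonist follistatin (4.61-fold), and the integrin gene Itga8 (4.38-fold). Mrgprf rested on 1 library: its log2 fold change of 2.33 ± 0.46 was 3.06 without BMP2 replicate 1 and 0.85, past no threshold, without BMP2 replicate 2. The other largest falls were the interferon-induced genes Usp18 (9.94-fold lower), Gbp7 (9.08-fold lower), Ifi203 (8.80-fold lower), Isg15 (8.31-fold lower) and Irf7 (7.32-fold lower).

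Of 20 inflammatory targets of NF-kB, 15 fell and 0 rose, and 16 fell when adjusted over the list alone (median −0.83, adjusted p = 1.11e-11, and adjusted p = 0.0458 with an estimated correlation). The chemokine genes Cxcl5, Cxcl1 and Ccl2 changed by −2.38 ± 0.12, −1.32 ± 0.10 and −0.82 ± 0.06. Of 24 sarcomere and calcium-handling genes, 22 fell and 0 rose, or 23 adjusted over the list alone (median −0.43, adjusted p = 2.53e-12, and adjusted p = 0.0458 with an estimated correlation). Among them were cardiac alpha-actin, Actc1 (6763 ± 47.2 to 3162 ± 0.528 CPM), and the ryanodine receptor gene Ryr2 (−0.99 ± 0.05). Myh6, the main adult cardiac myosin heavy chain gene, changed by −0.18 ± 0.03. Of 14 genes of the fetal and stress programme, 11 fell and 0 rose, also 11 adjusted over the list alone (median −0.85, adjusted p = 8.22e-10, and adjusted p = 0.0716 with an estimated correlation). The natriuretic peptide gene Nppb fell from 251 ± 5.72 to 71.6 ± 2.14 CPM and Nppa from 2452 ± 128 to 1079 ± 20.8 CPM. For Nppa, 61.5% of exonic bases lie within the opposite-strand model Gm13054, whose reads cannot be told apart from its own here.

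Of 18 BMP-SMAD target genes, 6 rose and 0 fell, or 7 and 2 adjusted over the list alone (median 0.23, adjusted p = 0.0342). That call was lost with an estimated correlation (adjusted p = 0.179) and in 5 of 6 fits without 1 library, with adjusted p up to 0.208 without BMP2 replicate 2. Id2, a transcriptional inhibitor, rose by 0.57 ± 0.10, the BMP pseudoreceptor gene Bambi by 0.65 ± 0.12 and the cardiac transcription factor gene Tbx20 by 0.84 ± 0.05. Smad6, an inhibitory SMAD, rose by 0.29 ± 0.09 and lost its call without PBS replicate 1 (0.19) or BMP2 replicate 2 (0.17). Id1 (−0.15 ± 0.11), Id3 (0.17 ± 0.07), Smad7 (0.01 ± 0.09) and Atoh8 (0.01 ± 0.10) did not pass the test. Clu, which encodes the chaperone clusterin, fell from 452 ± 12.5 to 274 ± 10.6 CPM (−0.72 ± 0.05). It was the 1 member of 12 called in the clusterin and TLR4 list, whose test did not pass (adjusted p = 0.856). Tlr4 (−0.24 ± 0.16), Bmp2 (0.32 ± 0.33), Bmpr1a (0.05 ± 0.07) and the proliferation marker Mki67 (0.01 ± 0.06) did not pass.

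Extracellular matrix and TGF-beta response genes moved in both directions: 20 of 22 fell and 2 rose, with the same counts adjusted over the list alone (median −0.42, adjusted p = 1.74e-08, and adjusted p = 0.15 with an estimated correlation). Those that rose were Thbs2 (1.53 ± 0.06) and Postn (0.69 ± 0.05), both encoding matricellular proteins, while the TGF-beta binding protein gene Ltbp2 fell by 1.66 ± 0.11. Wnt targets rose in 5 of 11 and fell in 1, or 6 and 1 adjusted over the list alone (adjusted p = 0.00521, and adjusted p = 0.15 with an estimated correlation), with Nkd1 at 1.49 ± 0.22 and Nkd2 at 0.94 ± 0.13, both Wnt feedback inhibitors. Of 20 fatty acid oxidation genes 9 rose and 1 fell, or 10 and 2 adjusted over the list alone, and of 21 nuclear-encoded oxidative phosphorylation genes 10 rose and 0 fell, or 12 and 0 (adjusted p = 0.00478 and 0.00197; with an estimated correlation, adjusted p = 0.15 and 0.342). Of 24 G2/M and mitosis genes, 0 were called, and the list did not pass (adjusted p = 0.67).

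Markers of other cells also moved. Epicardial and mesothelial markers fell in 6 of 10 and rose in 1, with the same counts adjusted over the list alone (adjusted p = 0.00521, and adjusted p = 0.15 with an estimated correlation), with Krt18 at −1.61 ± 0.15 and Upk3b at −2.34 ± 0.29. Fibroblast markers fell in 6 of 14 and rose in 2, or 8 and 2 adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.167 with an estimated correlation; adjusted p = 0.0646 without BMP2 replicate 2), with Thy1 at −1.14 ± 0.07 and Col3a1 at 0.54 ± 0.05. Endothelial markers (1 up and 1 down of 14, or 2 and 2 adjusted over the list alone) and leukocyte markers (0 up and 1 down of 10, likewise 0 and 1) did not pass as sets. Of 31 lists, 7 were called higher and 12 lower, of which 3 were kept with estimated correlations. In total 942 genes rose and 1335 fell, of which 105 and 331 changed at least 2-fold. With the 2 libraries high in ribosomal-repeat reads left out, 171 rose and 403 fell, a comparison of 1 library with 1 whose spread came from the BMP2+DM pair. Of the lists, 18 of 20 interferon-stimulated genes, 17 of 24 sarcomere genes, 16 of 22 matrix genes, 10 of 14 fetal and stress genes and 9 of 20 NF-kB targets still fell. Calls for 1 of 18 BMP-SMAD targets, 1 of 20 fatty acid oxidation genes and 4 of 21 oxidative phosphorylation genes remained, with medians of 0.27, 0.20 and 0.16 against 0.23, 0.20 and 0.15 in all libraries, and these lists were still called (adjusted p = 0.0306, 0.0413 and 0.0166). Of Wnt targets 3 of 11 rose (median 0.27 against 0.43), and 3 of 10 epicardial (−0.77 against −0.97) and 4 of 14 fibroblast markers (−0.21 against −0.20) fell, these lists too being called. Against a minimum fold of 1.5, 56 rose and 235 fell.

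**Figure D1:**
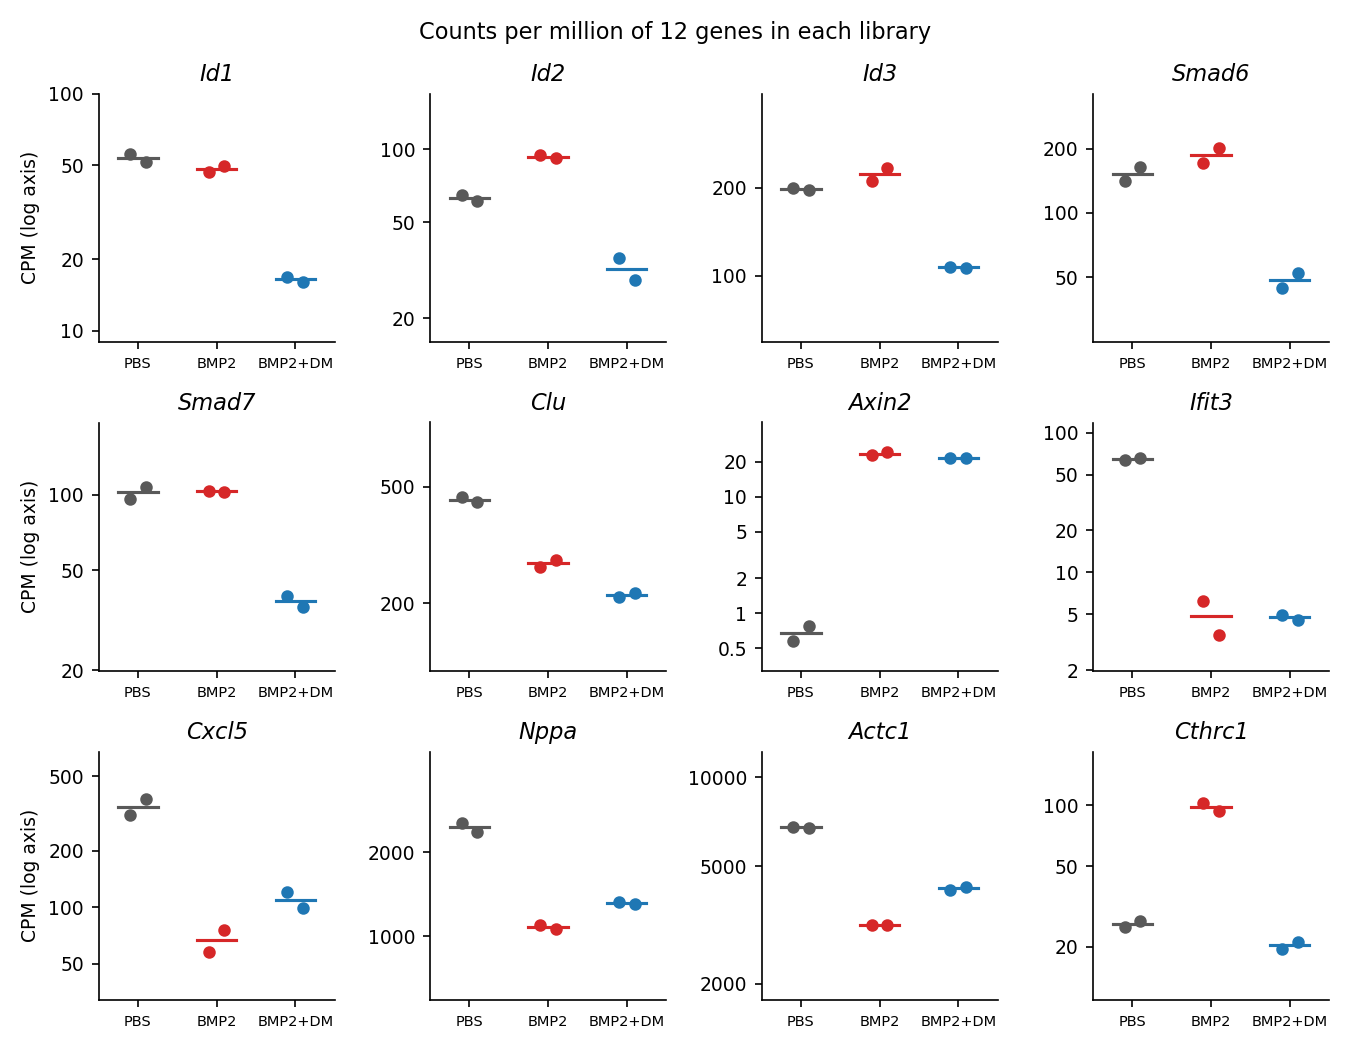
Normalised CPM (log axis) of 12 genes; each dot is 1 library and each line a group mean of 2 libraries. Id1, Id3, Smad6 and Smad7 sit lowest in BMP2+DM, Axin2 is high in both groups given BMP2 (23.6 and 21.7 against 0.678 CPM), and Cthrc1 is high with BMP2 alone (98.1 CPM).

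BMP2+DM against BMP2 asks which of the transcripts in BMP2-treated cells depend on signalling that dorsomorphin blocks; with no group given dorsomorphin alone, its other effects are included. BMP-SMAD target genes fell: 11 of 18 fell and 1 rose, or 12 and 1 adjusted over the list alone (median −0.80, adjusted p = 2.4e-10, and adjusted p = 0.0834 with an estimated correlation). Smad6 went from 186 ± 21.3 to 48.7 ± 5.48 CPM (SD, n = 2), a log2 fold change of −1.93 ± 0.10; the gene lies on the minus strand of chromosome 9 (63953076 to 64022059, mm10). Id1 and Id2 each fell by 1.54 on the log2 scale (± 0.13 and ± 0.11), Id3 by 1.06 ± 0.07, Smad7 by 1.46 ± 0.10, Atoh8 by 0.89 ± 0.11 and Tbx20 by 1.11 ± 0.05. Clu fell by a further 0.36 ± 0.05, to 213 ± 3.92 CPM.

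The largest rises were Syt13 (4.34-fold), the chemokine gene Ccl20 (4.31-fold), Aldh3a1 (4.28-fold), Vegfd, a vascular growth factor gene (4.01-fold), Galnt16 (3.84-fold), Mylk4 (3.49-fold), Krt7 (3.49-fold) and Vnn1 (3.48-fold). The largest falls were the splicing regulator gene Rbfox1 (8.56-fold lower), the endothelial gene Esm1 (6.89-fold lower), Megf10 (5.51-fold lower), Cthrc1 (4.81-fold lower), the hyaluronan-related genes Hapln1 (4.64-fold lower) and Has2 (4.63-fold lower), and Ndnf (4.18-fold lower, and log2 −2.75 without BMP2+DM replicate 1). The rule also named the ribosomal-repeat model AY036118 (−4.04 ± 1.06), which was decided by 1 library: without BMP2 replicate 1 it was −0.29 (adjusted p = 0.9). That model lies wholly within the opposite-strand model Gm42418.

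Sterol synthesis and uptake genes rose in 12 of 21 with 0 falls, or 13 and 0 adjusted over the list alone (median 0.43, adjusted p = 8.26e-09, and adjusted p = 0.0834 with an estimated correlation), among them Cyp51 (0.57 ± 0.09) and Msmo1 (0.76 ± 0.12), both sterol pathway enzymes. Fatty acid oxidation genes rose in 11 of 20 with 0 falls, or 15 and 0 (median 0.28, adjusted p = 7.95e-08, and adjusted p = 0.0834 with an estimated correlation), with the transport genes Cd36 at 0.48 ± 0.07 and Cpt1b at 0.43 ± 0.07. Sarcomere and calcium-handling genes rose in 11 of 24 with 0 falls, or 12 and 1 (median 0.10, adjusted p = 0.00131, and adjusted p = 0.155 with an estimated correlation), with Myom2 at 1.51 ± 0.08 and Actc1 at 0.41 ± 0.04. Matrix and TGF-beta response genes fell in 14 of 22 and rose in 5, with the same counts adjusted over the list alone (median −0.34, adjusted p = 5.87e-05, and adjusted p = 0.266 with an estimated correlation), among them the tenascin gene Tnc (−1.05 ± 0.06).

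Endothelial markers fell in 5 of 14 with 0 rises, or 7 and 0 adjusted over the list alone (median −0.38, adjusted p = 5.64e-06, and adjusted p = 0.155 with an estimated correlation), with Kdr at −1.41 ± 0.20 and Ptprb at −0.99 ± 0.10. Epicardial and mesothelial markers rose in 3 of 10 and fell in 1, or 5 and 1 adjusted over the list alone (adjusted p = 0.0184, and adjusted p = 0.248 with an estimated correlation; kept in 4 of 6 fits without 1 library, adjusted p = 0.0582 without BMP2+DM replicate 1), with Msln at 1.44 ± 0.20 and Lrrn4 at −1.12 ± 0.13. Dkk2, a Wnt inhibitor gene, had 33 counts over both BMP2 libraries and 0 over both BMP2+DM libraries. Set against a floor of 3 counts over the group, it was at least 10.4-fold lower; the floor covers counting error only. Of 31 lists, 6 were called higher and 6 lower, of which 0 were kept with estimated correlations. In total 616 genes rose and 639 fell, 90 and 128 of them at least 2-fold. With the 2 libraries high in ribosomal-repeat reads left out, 137 rose and 176 fell; 9 of 18 BMP-SMAD targets, 12 of 22 matrix genes and 2 of 14 endothelial markers were still called lower (medians −0.97, −0.35 and −0.40), and 3 of 21 sterol, 4 of 20 fatty acid oxidation and 9 of 24 sarcomere genes higher (medians 0.39, 0.27 and 0.13). All 6 lists were still called, with adjusted p = 2.09e-05 for sterol, 5.87e-05 for fatty acid oxidation, 0.0376 for sarcomere and 0.000633 for endothelial genes. Against a minimum fold of 1.5, 38 rose and 60 fell.

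**Figure D2:**
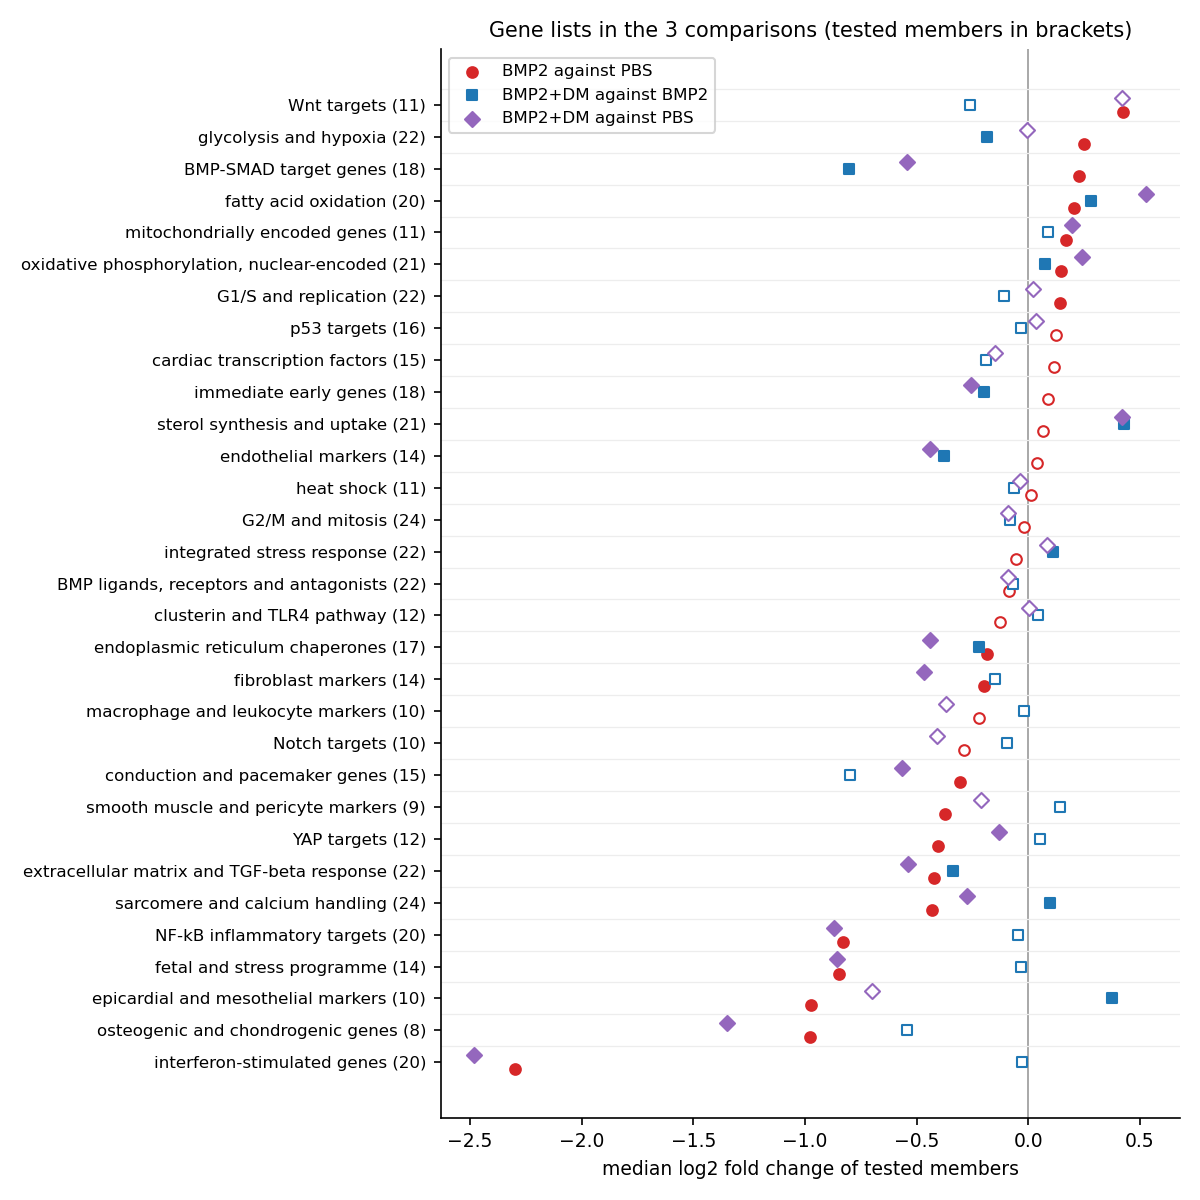
Median log2 fold change of each tested gene list in the 3 comparisons, with the number of tested members in brackets; filled symbols passed camera with the preset correlation and open symbols did not. Interferon-stimulated genes lie at −2.30 and −2.48 against PBS in the groups without and with dorsomorphin, and BMP-SMAD targets at −0.80 in BMP2+DM against BMP2.

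The part of the BMP2 response that dorsomorphin moved back was counted over the 2277 genes called in BMP2 against PBS. Of these, 380 (16.7%) were called in the opposite direction when dorsomorphin was added: 132 that had risen and 248 that had fallen. Independent lists of these sizes would share 41.9 and 57.2. Simulations with the BMP2 effects as fitted and dorsomorphin without effect called a mean of 3420 genes with BMP2. They gave a mean of 0.4 opposite calls and at most 2, and a mean of 0.15 calls in the same direction. Hardly any gene could be called for dorsomorphin in them. They therefore bear on whether dorsomorphin changed genes, not on whether it moved BMP2 changes back. Cthrc1, which encodes a secreted matrix-associated protein, went from 25.95 ± 1.22 CPM with PBS to 98.1 ± 6.50 with BMP2 and 20.4 ± 1.15 with both. Tbx20 went from 795 ± 12.4 to 1421 ± 19.8 and 657 ± 34.2 CPM. Igfbp5, Fst and Ndnf also fell back, with Fst still 1.31 above PBS on the log2 scale. Cxcl5, Nppb and Actc1 rose back in part. In BMP2+DM against PBS, 264 of the 380 genes were not called, 89 were still called on the BMP2 side and 27 on the other side.

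A further 196 genes (8.61%) were called in the direction of the BMP2 change, 56 upward and 140 downward, against 40.4 and 59.3 for independent lists. Nkd1 (6.28 ± 2.32, 17.4 ± 3.56 and 45.2 ± 1.25 CPM) and Itga8 were among those that rose again, and Clu, Esm1 and Rbfox1 among those that fell again. The covariance of the BMP2 and dorsomorphin fold changes across genes was −0.0904, against −0.0396 in these simulations (a difference of −0.0508) and −0.0367 in simulations with no effect in any group (a difference of −0.0537); genes are not independent replicates. Both fold changes use the same BMP2 libraries. With a different BMP2 library in each fold change, the covariance was −0.0199 and −0.0176, against −0.0632 for the same log2 CPM with shared libraries. In the same 2 splits, 309 and 304 genes with mean log2 CPM of at least 2 lay at least 2-fold from PBS. Of these, 66.7% and 60.5% changed in the opposite direction with dorsomorphin. The median ratio of the dorsomorphin change to the BMP2 change was −0.139 and −0.0896. With the 2 ribosomal-repeat libraries left out, 76 genes were moved back, and leaving out 1 library gave 219 (without BMP2 replicate 1) to 293.

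BMP2+DM against PBS shows what differed from untreated cells when both were present. Axin2 stayed high, at 21.7 ± 0.0806 CPM (32.0-fold), and Nkd1 (7.29-fold), Itga8 (6.52-fold), Itih5 (6.27-fold) and Syt13 (5.62-fold) were the other largest rises. Ifit1 (24.0-fold lower), Rtp4 (21.1-fold lower), Usp18 (14.9-fold lower), Rbfox1 (14.6-fold lower) and Esm1 (14.2-fold lower) were the largest falls. All 20 interferon-stimulated genes fell, also adjusted over the list alone (median −2.48, adjusted p = 1.95e-16, and adjusted p = 0.0587 with an estimated correlation), and 15 of 20 NF-kB targets fell with 0 rises, or 18 adjusted over the list alone (adjusted p = 1.19e-10, and adjusted p = 0.0587 with an estimated correlation).

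BMP-SMAD targets lay below PBS in 11 of 18 and above it in 1, with the same counts adjusted over the list alone (median −0.54, adjusted p = 3.76e-05, and adjusted p = 0.0702 with an estimated correlation). Id1 (−1.69 ± 0.13), Smad6 (−1.64 ± 0.10), Smad7 (−1.44 ± 0.10), Id2 (−0.98 ± 0.11), Id3 (−0.89 ± 0.07) and Atoh8 (−0.88 ± 0.10) were all below PBS. Fatty acid oxidation genes rose in 15 of 20 with 0 falls, or 19 and 0 (median 0.53, adjusted p = 9.85e-10, and adjusted p = 0.0587 with an estimated correlation), with Fabp3 at 0.86 ± 0.06. Oxidative phosphorylation genes rose in 16 of 21 with 0 falls, or 17 and 0 (adjusted p = 9.75e-06, and adjusted p = 0.202 with an estimated correlation). Sarcomere genes were below PBS in 18 of 24 and above it in 1, or 19 and 2 (adjusted p = 2.65e-05, and adjusted p = 0.0702 with an estimated correlation), with Actc1 at −0.69 ± 0.04, Myh6 at −0.09 ± 0.03 and, in the fetal and stress list, Nppa at −0.90 ± 0.05. Clu was at −1.08 ± 0.05. Tlr4 (−0.05 ± 0.16), Bmp2 (−0.49 ± 0.35), Bmpr1a (0.07 ± 0.07) and Mki67 (0.04 ± 0.06) did not pass.

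In total 1349 genes rose and 1658 fell, 161 and 435 at least 2-fold. Of the genes that rose with BMP2 against PBS, 553 (58.7%) were also above PBS with dorsomorphin. Of those that fell, 884 (66.2%) were also below. Independent lists would share 88.4 and 154; both comparisons use the same PBS libraries. Simulations with BMP2 effects as fitted and dorsomorphin without effect shared a mean of 2500 calls of 3420 genes called with BMP2, against 1437 of 2277 here. The covariance of the 2 sets of fold changes was 0.224. It was 0.337 in these simulations (a difference of −0.113) and 0.0344 in simulations with no effect in any group (a difference of 0.189). The simulations with BMP2 effects add noise to fitted means that already hold noise, and so overstate those effects. The distance of the observed values from them is therefore not a measure of dorsomorphin alone. Endothelial markers were below PBS in 7 of 14 with 0 above, or 8 and 0 adjusted over the list alone (adjusted p = 0.00501, and adjusted p = 0.157 with an estimated correlation). Fibroblast markers were below in 9 of 14 and above in 3, likewise 9 and 3 (camera adjusted p = 0.00501, and 0.117 with an estimated correlation). Mitochondrially encoded genes were above in 6 of 11 with 0 below, or 8 and 0 (camera adjusted p = 0.00203, and 0.315 with an estimated correlation). Of 31 lists, 4 were called higher and 13 lower, of which 0 were kept with estimated correlations. Against a minimum fold of 1.5, 95 rose and 329 fell, and with the 2 ribosomal-repeat libraries left out, 533 rose and 855 fell; 16 of 20 interferon-stimulated genes, 10 of 20 NF-kB targets, 11 of 18 BMP-SMAD targets, 15 of 24 sarcomere genes and 4 of 14 endothelial markers were still called lower (medians −2.56, −0.81, −0.56, −0.29 and −0.39), and 9 of 20 fatty acid oxidation and 11 of 21 oxidative phosphorylation genes higher (medians 0.49 and 0.30), and each of these lists was still called.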

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

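No test was chosen after this result was seen. A difference between groups was seen in a part of the files outside the comparisons. Reads without a unique alignment, which enter no comparison, took 4.22% of the total in BMP2 (SD 0.245, n = 2) and 4.25% in BMP2+DM (SD 0.176, n = 2), above both PBS libraries (3.99% and 3.80%, mean 3.90%). Replicates 1 and 2 were at 4.388% and 4.042% in BMP2 and at 4.374% and 4.125% in BMP2+DM. Replicate 1 was above replicate 2 in each group, PBS included. With 2 libraries per group, the difference was not tested.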

How the results depend on the processing

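Of the alternatives, only leaving out the 2 ribosomal-repeat libraries, or their gene models, was chosen after the data were seen. Of 373 named results, 357 were called and none of these turned direction in any alternative, and 132 stayed past the threshold in every one. Deviations from the group mean were little correlated between libraries of the same replicate number (0.128, −0.0448 and −0.00235). This does not show that the samples are unpaired, and both libraries high in ribosomal-repeat reads were replicate 1. With the replicate numbers as a block, 932 rose and 1329 fell with BMP2. With dorsomorphin against BMP2 the counts were 601 and 625, and with both against PBS 1327 and 1633. DESeq2 called 1842, 1043 and 2406 genes. A minimum fold of 1.5 left 291 (56 up, 235 down), 98 (38, 60) and 424 (95, 329). With estimated correlations, which also bring in the 3 residual degrees of freedom, 3 lists (0 higher, 3 lower), 0 (0, 0) and 0 (0, 0) were called. Without the 2 libraries, which leaves 1 library in each of 2 groups, genes called were 574 (171, 403), 313 (137, 176) and 1388 (533, 855), and 76 moved back. The covariance with all libraries in log2 CPM, −0.0632, was −0.0199 and −0.0176 with disjoint BMP2 libraries. In the ranges that follow, the upper ends for genes called come from leaving out a library of the group outside the comparison. Leaving out a library of a compared group lowered the number of genes called every time. Leaving out 1 library, whose partner is then assumed to vary like the other groups, gave 1318 to 2470 (475 to 1028 up, 843 to 1442 down) with BMP2, 670 to 1081 (314 to 528, 356 to 553) with dorsomorphin against BMP2, and 1827 to 2928 (742 to 1298, 1085 to 1630) against PBS; 219 to 293 moved back; and lists called were 13 to 17 (4 to 6 higher, 9 to 11 lower), 9 to 12 (3 to 5, 6 to 7) and 17 to 19 (4 to 4, 13 to 15). Uncalled genes near 0 changed sign: with BMP2 against PBS, Atoh8 (−0.0206 to 0.037), Bmpr1a (−0.0121 to 0.101), Mki67 (−0.0348 to 0.0535) and Smad7 (−0.0653 to 0.0963); with BMP2+DM against BMP2, Bmpr1a (−0.0542 to 0.107), Mki67 (−0.0464 to 0.109) and Tlr4 (−0.0162 to 0.39); with BMP2+DM against PBS, Bmpr1a (−0.00942 to 0.152), Mki67 (−0.0377 to 0.118) and Tlr4 (−0.25 to 0.13). Without the 2 libraries, Smad7, Atoh8 and Bmpr1a were −0.0736, −0.0344 and −0.0295 with BMP2 and Mki67 was −0.0104 with dorsomorphin against BMP2. The causes of these moves were not tested. Depth limits genes such as Dkk2, with 0 counts in a group.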

Other observations

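Of the tests in this part, those on overlapping genes and on strand were set before their results were seen; those on Wnt targets, leukocytes and ribosomal-repeat libraries were chosen afterwards.

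Other groups of genes moved as well. Glycolysis and hypoxia genes rose with BMP2 in 12 of 22 and fell in 1, or 13 and 3 adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.377 with an estimated correlation; adjusted p = 0.0776 without BMP2 replicate 2). In BMP2+DM against BMP2, 8 fell and 2 rose, or 12 and 2 adjusted over the list alone (adjusted p = 0.0184, and adjusted p = 0.383 with an estimated correlation; kept in 4 of 6 fits without 1 library, adjusted p = 0.0582 without BMP2+DM replicate 1), with the lactate transporter gene Slc16a3 at −1.49 ± 0.12. Endoplasmic reticulum chaperone genes fell in 6 of 17 with BMP2 and in 10 of 17 with BMP2 and dorsomorphin, against PBS, with 0 rises, or 9 and 11 adjusted over the list alone (adjusted p = 0.00521 and 1.82e-05; with an estimated correlation, adjusted p = 0.15 and 0.0702). YAP targets fell in 7 of 12 with BMP2, or 8 adjusted over the list alone (adjusted p = 0.00026, and adjusted p = 0.146 with an estimated correlation), among them Ankrd1 at −0.98 ± 0.05. Osteogenic and chondrogenic genes fell in 6 of 8 with BMP2, also 6 adjusted over the list alone (adjusted p = 0.000889, and adjusted p = 0.167 with an estimated correlation), with Alpl, the bone alkaline phosphatase gene, at −2.04 ± 0.29 and Sox9 at −0.79 ± 0.12. Immediate early genes fell in 8 of 18 and rose in 1 when dorsomorphin was added, with the same counts adjusted over the list alone (adjusted p = 0.0184, and adjusted p = 0.248 with an estimated correlation). With BMP2 alone their median (0.09) and the direction of the test (down, adjusted p = 0.856) differed in sign. Mitochondrially encoded genes rose in 4 of 11 with BMP2, or 8 adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.466 with an estimated correlation).

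Conduction and pacemaker genes fell in 7 of 15 and rose in 2 with BMP2, or 9 and 2 adjusted over the list alone (adjusted p = 0.0339, and adjusted p = 0.179 with an estimated correlation; kept in only 2 of 6 fits without 1 library, adjusted p = 0.089 without PBS replicate 2), and fell in 8 and rose in 1 against PBS with dorsomorphin, or 9 and 1 (adjusted p = 0.000109, and adjusted p = 0.0762 with an estimated correlation). The contactin gene Cntn2 had 43, 4 and 90 counts per group with PBS, BMP2 and BMP2+DM, and the sodium channel gene Scn10a had 148, 8 and 47. G1/S and replication genes rose in 4 of 22 and fell in 1 with BMP2, with the same counts adjusted over the list alone (adjusted p = 0.0235, and adjusted p = 0.167 with an estimated correlation; kept in 4 of 6 fits without 1 library, adjusted p = 0.146 without BMP2 replicate 2). Smooth muscle and pericyte markers fell in 4 of 9 and rose in 2, or 5 and 2 adjusted over the list alone (adjusted p = 0.0421, and adjusted p = 0.2 with an estimated correlation; kept in only 1 of 6 fits without 1 library and in 1 of 3 with RLE factors, no count filter or the block, adjusted p = 0.095 without BMP2 replicate 1). Integrated stress response genes rose in 4 of 22 and fell in 1 with dorsomorphin against BMP2, or 5 and 2 adjusted over the list alone (adjusted p = 0.0462, and adjusted p = 0.304 with an estimated correlation; kept in only 1 of 6 fits without 1 library, adjusted p = 0.228 without BMP2+DM replicate 2 and 0.0765 with the replicate block). With BMP2 against PBS, the lists of BMP ligands, receptors and antagonists (adjusted p = 0.484), cardiac transcription factors (0.337), heat shock (0.912), p53 targets (0.139) and Notch targets (0.246) did not pass as sets. Schwann cell and neuronal markers had 0 of 4 called. With the 2 ribosomal-repeat libraries left out, calls with BMP2 remained for 0 of 17 endoplasmic reticulum chaperone genes, 2 of 8 osteogenic genes and 4 of 12 YAP targets, while the medians were −0.21, −1.07 and −0.32, against −0.19, −0.98 and −0.40 in all libraries, and these lists were still called (adjusted p = 0.0306, 0.0166 and 0.0081). The glycolysis and hypoxia list, with 6 of 22 called higher and a median of 0.25 as before, was not (adjusted p = 0.0831). Nor were smooth muscle and pericyte markers with BMP2 (adjusted p = 0.145) or, in BMP2+DM against BMP2, glycolysis and hypoxia (0.0737) and integrated stress response genes (0.129).

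Axin2 was high in both groups given BMP2. Reads from an overlapping gene are argued against, since only 3.8% of its exonic bases lie within another model. A rise of Wnt targets as a set stays open: of the other 10 members 4 rose and 1 fell with BMP2 (median 0.41, adjusted p = 0.0344, and adjusted p = 0.193 with an estimated correlation), and with dorsomorphin added the set did not pass against PBS (median 0.12, adjusted p = 0.56). An effect of BMP2 itself stays open, and the design cannot tell it from another difference between the PBS libraries and the rest. In BMP2+DM against BMP2, Axin2 was at −0.12 ± 0.16 and did not pass.

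Interferon-stimulated genes were low in both groups given BMP2. If leukocytes themselves held these transcripts, fewer leukocytes would lower leukocyte markers by a like amount. But the median of the 10 markers, none of them in another list, was −0.221 (quartiles −0.57 and −0.02) with BMP2. With dorsomorphin added it was −0.37 (quartiles −0.56 and 0.10), against −2.30 and −2.48 for the interferon genes. Against PBS, 1 marker fell with BMP2 and 2 with dorsomorphin added, or 1 and 4 adjusted over the list alone, with 0 rises. These values do not cover an effect of leukocytes on transcripts of other cells. Without PBS replicate 2 the macrophage and leukocyte markers were called lower (adjusted p = 0.0199 with BMP2 and 0.0069 with BMP2+DM, against PBS), with medians of −0.59 in each, against −2.29 and −2.39 for the interferon genes. The 2 libraries high in ribosomal-repeat reads stay open: without them the median was −2.329 with BMP2 and −2.56 with BMP2+DM, but the upper quartiles (−1.12 and −1.10) missed the bound set for excluding them, and the 18 calls of 20 with BMP2 compare 1 library with 1, with the spread of the BMP2+DM pair. An effect of BMP2 itself stays open too. The design cannot tell it from another difference between the PBS libraries and the rest. In BMP2+DM against BMP2, the median of the interferon genes was −0.03, with 3 of 20 called higher and 2 lower.

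Reads assigned to no gene made up 49.7% to 50.2% of each library. In 112 genes with at least 90% of their exonic bases inside exons of an opposite-strand gene, the count density was a median 1.43 times that of the partner (quartiles 0.911 and 2.13), with 52.7% between 0.5 and 2. This is consistent with counting by strand of libraries that carry no strand information, which may have left a like share of reads uncounted in every library alike. No biological explanation was tested.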
